A study of Sus scrofa with 13 samples.

How the data were processed

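The study compared mesenchymal stem cells from the fat of hypercholesterolaemic pigs with renal artery stenosis, cultured at 1% or 20% oxygen. Per the labels' protocols, DNA was treated with RNase during extraction, sonicated, denatured and incubated with an anti-5hmC antibody. Libraries were made from the single-stranded product with a Swift ACCEL-NGS 1S kit and sequenced from both ends on a HiSeq4000. Samples were grouped by the treatment label. The labels also list 1 input sample, which belongs to no group and was not analysed here.

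The submitters' processing notes name Bowtie2, MACS2, Picard, HTSeq and edgeR without versions or settings. The authors deposited, per library, a table of raw HTSeq counts per gene symbol and a MACS2 peak list. Per the labels' tool list and the column order, each peak in the deposited lists has a fold enrichment (a ratio), a −log10 p-value and −log10 q-value, and a score. These are the authors' values and were used only to rank or filter peaks within a list. Peaks were deposited as 1 list per library. The genome build, the gene annotation, the HTSeq feature type and strand setting, and the MACS2 control are not given in the sources used here. The reads come from DNA, so their strand does not tell overlapping genes on opposite strands apart. Without a named feature type, it is not stated whether the counts cover exons or whole genes. Across the libraries, 1.69 to 2.89% of reads fell in genes and 88 to 93% outside any feature. So low a share argues against counts over whole genes, and the gene values below may leave out signal in introns.

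The tables held 27339 gene rows, of which 26838 matched a symbol in the RefSeq table of assembly Sscrofa11.1. That table was used for names and for gene neighbours, and none of its coordinates are printed. Rows that name no gene were left out of library sizes and tests. The row for reads outside any feature held 88 to 93% of reads, that for low alignment quality 4.12 to 10.3%, and a row with a blank name 0 reads. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 1.26 over 66 pairs).

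Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a total of 15, TMM scaling, glmQLFit and glmQLFTest), with an adjusted p threshold of 0.05. CPM are gene counts scaled by edgeR to TMM-adjusted library sizes, computed here from the deposited counts, and fold changes carry edgeR's SE (the log2 fold change over the root of F). The 17 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Of the 57 HIF targets 5 and of the 44 matrix genes 3 are also on another list. The tests of the 3 comparisons, the lists and the rule for named genes were fixed before the data were examined, and tests added later are named with their results.

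The rule named up to 10 called genes per direction, then the genes with the smallest p up to 5 per direction, for both fits. It added the TET and DNMT genes, HIF1A, EPAS1, VEGFA, the 2 members of each list with the smallest p, and members passing over their list alone, both in the fit without the block. HK2, NDRG1, BNIP3L, GAPDH, KDM3A, COL12A1, COL3A1, SMAD3, HS3ST3B1 and ACKR3 were chosen after their values were seen. Regions were ranked by the difference in libraries with a peak, then by length.

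By the rule set beforehand, the title numbers paired the libraries, with doubt for numbers 33 and 4. After the group means were removed, log2 CPM of the libraries sharing a number correlated across genes at 0.136 to 0.478 (mean 0.362). All were above the threshold of 0.1 set beforehand. Their mean was high among 720 arrangements of the numbers (one-sided exact permutation p = 0.00278). The mean for other pairs, -0.0727, is pulled below 0 by the removal of the group means and is no separate evidence. Single other pairs reached 0.504. The pairing comes from the numbers that start the titles. What a number stands for is not stated, so p-values measure the spread between these libraries, which may be technical. The fit with the number as a block is printed beside a result where it changed a call. The biological coefficient of variation was 0.305 without and 0.21 with the block.

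The fit was tested on simulated counts for the 11868 genes with 6 pairs of libraries, 67 or 66 genes changed at each fold. Without the block it recovered 0% of genes changed 1.5-fold, 23.9% of those changed 2-fold and 78.8% of those changed 3-fold. With the block it recovered 11.9, 58.2 and 80.3%, and 1% of its calls were unchanged genes. Without the block, most simulated 2-fold changes were thus not recovered. The simulation used the dispersions of the blocked fit, a pair effect of assumed size, correct pairing and no outlying library. These shares may therefore not hold for the real libraries.

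Peaks were compared with Python 3.11.15, pandas 2.3.3 and bedtools 2.31.1. Group means were compared with two-sided exact permutation tests, and correlations with permutation tests. Peaks of all libraries were merged where they shared at least 1 base. Alternatives were other scalings, no count filter, sequencing lane as a covariate, DESeq2 1.42.0, stricter peaks, other region definitions, each library or number left out, and counts thinned to 263578 gene reads. Shares of peaks in promoters and gene bodies, and a fit on autosomal and X-linked genes alone, were planned and not run, since no annotation of the files' build was at hand.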

Results

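5-hydroxymethylcytosine (5hmC), an oxidised form of DNA methylation, was profiled in mesenchymal stem cells grown from the abdominal fat of female pigs with diet-induced high cholesterol and a narrowed renal artery. DNA fragments carrying 5hmC were captured with an antibody and sequenced. The 6 hypoxia libraries came from cells kept at 1% oxygen for 48 hours before harvest, and the 6 normoxia libraries from cells kept at 20% oxygen. Each group held 1 library for each of the title numbers 110, 16, 21, 33, 49 and 4. The count tables held 15569948 to 27428482 reads per library, of which 1.69 to 2.89% fell in genes. In the number order 110, 16, 21, 33, 49 and 4, the hypoxia libraries held 457093, 353379, 402015, 552867, 511661 and 623108 gene reads, and the normoxia libraries 483233, 468136, 263578, 427261, 568257 and 714002. The share of reads in genes was 2.387 ± 0.167% in hypoxia and 2.477 ± 0.409% in normoxia (SD, n = 6 each).

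The first comparison asked at which genes hypoxia preconditioning altered the 5hmC signal of these cells. Without regard to the title numbers, 0 of 11868 tested genes passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, and 4 passed when the title number was a block. SFTA2, a surfactant-associated protein gene, PPP1R3C, which targets protein phosphatase 1 to glycogen, and SHMT2, the mitochondrial serine hydroxymethyltransferase, rose in hypoxia in the blocked fit, each in 6 of 6 numbers. LOC110260784, chosen after its values were seen because it has no symbol, fell in 6 of 6 numbers.

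SFTA2 rose from 9.16 ± 12.3 to 42.2 ± 34.9 CPM (mean ± SD, n = 6 per group), a blocked log2 fold change of 2.40 ± 0.416 (SE) with an edgeR adjusted p of 0.0237, on 0 to 51 reads per library. PPP1R3C rose from 65.0 ± 45.3 to 150 ± 77.0 CPM, with a blocked log2 fold change of 1.30 ± 0.239 and an adjusted p of 0.0237. SHMT2 rose from 61.0 ± 29.1 to 135 ± 46.1 CPM, with a blocked log2 fold change of 1.15 ± 0.215 and an adjusted p of 0.0237. LOC110260784 went from 191 ± 65.2 CPM in normoxia to 89.5 ± 29.5 CPM in hypoxia, with a blocked log2 fold change of -1.07 ± 0.200 and an adjusted p of 0.0237. In the fit without the block, SFTA2, PPP1R3C, SHMT2 and LOC110260784 had log2 fold changes of 2.15, 1.22, 1.13 and -1.09, each with an adjusted p of 1.

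**Figure D1:**
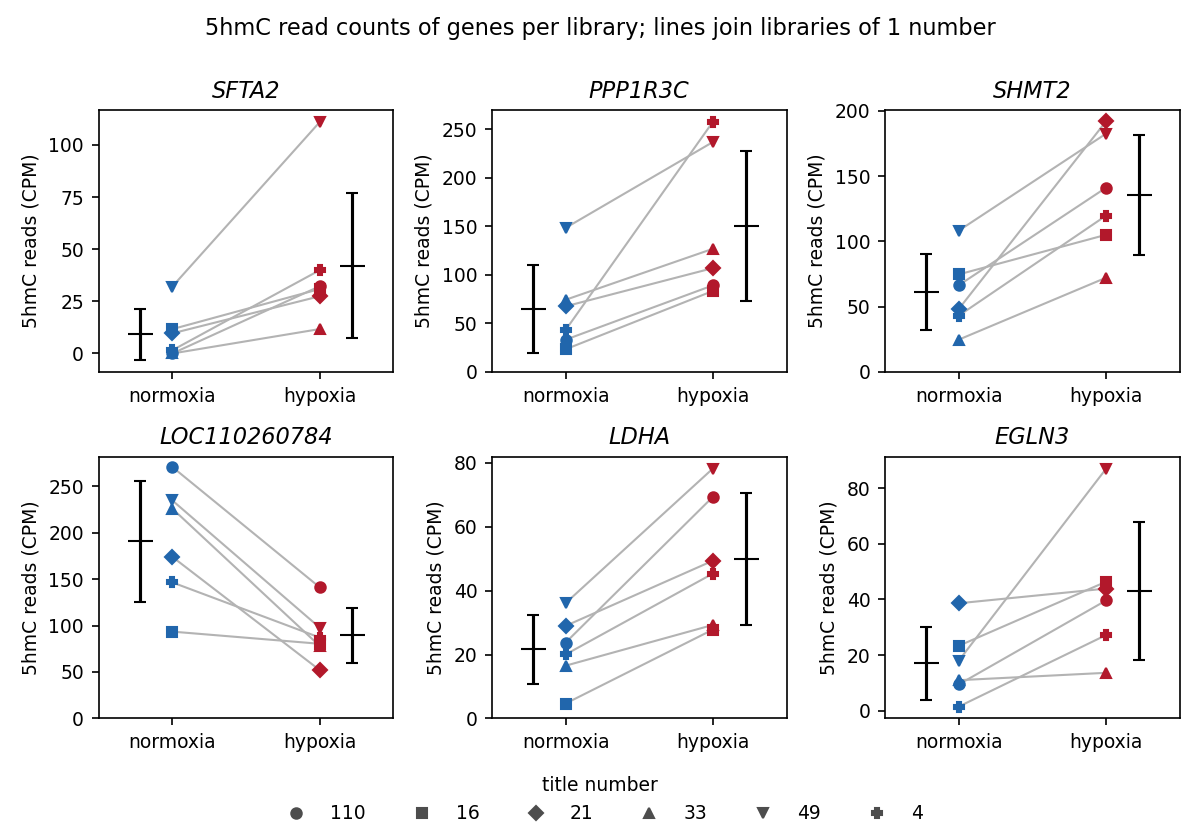
Normalised 5hmC read count (CPM) of the 4 genes called with the title number as a block, and of LDHA and EGLN3, in each library, with lines joining the normoxia and hypoxia libraries of 1 number and bars giving the mean ± SD of the 6 libraries of a group. SFTA2, PPP1R3C, SHMT2, LDHA and EGLN3 were higher in hypoxia in 6 of 6 numbers, and LOC110260784 was lower in 6 of 6.

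Further genes with the smallest p in the fit without the block did not pass the test. Among those with a higher count in hypoxia, DNAJC5G had a log2 fold change of 1.06 ± 0.307 (SE), C2CD2L 0.83 ± 0.243 and ZNF391 1.00 ± 0.294. Among those with a lower count, GMFB, encoding glia maturation factor beta, had -0.90 ± 0.272, PCNX4 -0.86 ± 0.267, PHYH, the peroxisomal phytanoyl-CoA hydroxylase, -1.17 ± 0.369, PPP4R4 -0.79 ± 0.249 and ANTXR1, an anthrax toxin receptor, -0.66 ± 0.215. In the blocked fit the transcriptional regulator JAZF1 came closest below the threshold, with a log2 fold change of -1.12 ± 0.227 and an adjusted p of 0.0569. The chemokine gene PPBP (-1.16 ± 0.251), MMD (-1.13 ± 0.257), the growth factor gene EREG (-0.89 ± 0.206) and FAM118B (-0.96 ± 0.225) followed, with adjusted p of 0.118 for PPBP and 0.172 for MMD, EREG and FAM118B.

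In all, 324 genes had an unadjusted p under 0.05 without the block, 109 higher and 215 lower in hypoxia, where 593 were expected by chance. With the block there were 841, 308 higher and 533 lower. With library size as the only scaling the direction of both splits turned, to 159 higher and 123 lower without the block and 468 higher and 371 lower with it. DESeq2's Wald test, run without the count filter, gave 0 calls. It had 512 of 25336 genes at an unadjusted p under 0.05, where 1267 is that share of all genes. Genes with few reads seldom reach such a p, so 1267 is too high as a chance count. The 4 genes kept their direction and size of change when both libraries of a number were left out, with blocked log2 fold changes of 2.05 to 2.71 for SFTA2, 0.98 to 1.49 for PPP1R3C, 1.03 to 1.33 for SHMT2 and -1.16 to -0.97 for LOC110260784. Their calls did not all hold with 10 libraries: leaving out 110, of 33 or of 4 left 0 calls, leaving out 49 left 1 (PPP1R3C), leaving out 16 left 3 (SFTA2, SHMT2 and LOC110260784), and leaving out 21 gave 12, with all 4 among them.

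Genes under control of the hypoxia-inducible factors (HIF) had, as a group, more 5hmC reads in hypoxia. Of 42 measured HIF target genes, 31 had a positive and 11 a negative log2 fold change without the block, with a median of 0.235 and a camera adjusted p of 3.47e-05. With the block, 35 were positive and 7 negative, with a median of 0.26 and a camera adjusted p of 9.59e-06. The call was lost with an estimated correlation, with adjusted p = 0.381 without and adjusted p = 0.485 with the block, and limma's directional fry gave adjusted p of 0.501 and 0.203. Among genes above the median of mean CPM the camera adjusted p was 0.103 without the block, and 0.0446 with it, where the median of HIF targets was 0.112. Leaving out number 4 in the blocked fit lowered the median to 0.165 (adjusted p = 0.011). No member passed over all genes tested or, without the block, adjusted over the list alone. In the blocked fit 4 passed adjusted over the list alone: LDHA, the lactate dehydrogenase of anaerobic glycolysis, EGLN3, an oxygen-sensing prolyl hydroxylase, HK2, a hexokinase, and NDRG1, a stress-response gene.

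LDHA had 49.9 ± 20.6 CPM in hypoxia and 21.7 ± 10.8 in normoxia (SD, n = 6 each), a blocked log2 fold change of 1.23 ± 0.289 (SE), and an edgeR adjusted p of 0.00425 over the list alone and 0.172 over all genes. EGLN3 had 43.0 ± 24.8 and 17.0 ± 13.0 CPM, a blocked log2 fold change of 1.51 ± 0.360, and adjusted p of 0.00425 over the list alone and 0.172 over all genes. HK2 (blocked log2 fold change 0.72) and NDRG1 (0.73) had adjusted p of 0.0279 and 0.0321 over the list alone. BNIP3L, a mitophagy receptor gene, went the other way with -0.60 ± 0.229, and GAPDH (0.01) and KDM3A (0.01) stood near 0. VEGFA, encoding a secreted growth factor of blood vessels, had 131 ± 68.4 CPM in hypoxia and 107 ± 62.2 in normoxia, a log2 fold change of 0.27 ± 0.370 without the block.

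**Figure D2:**
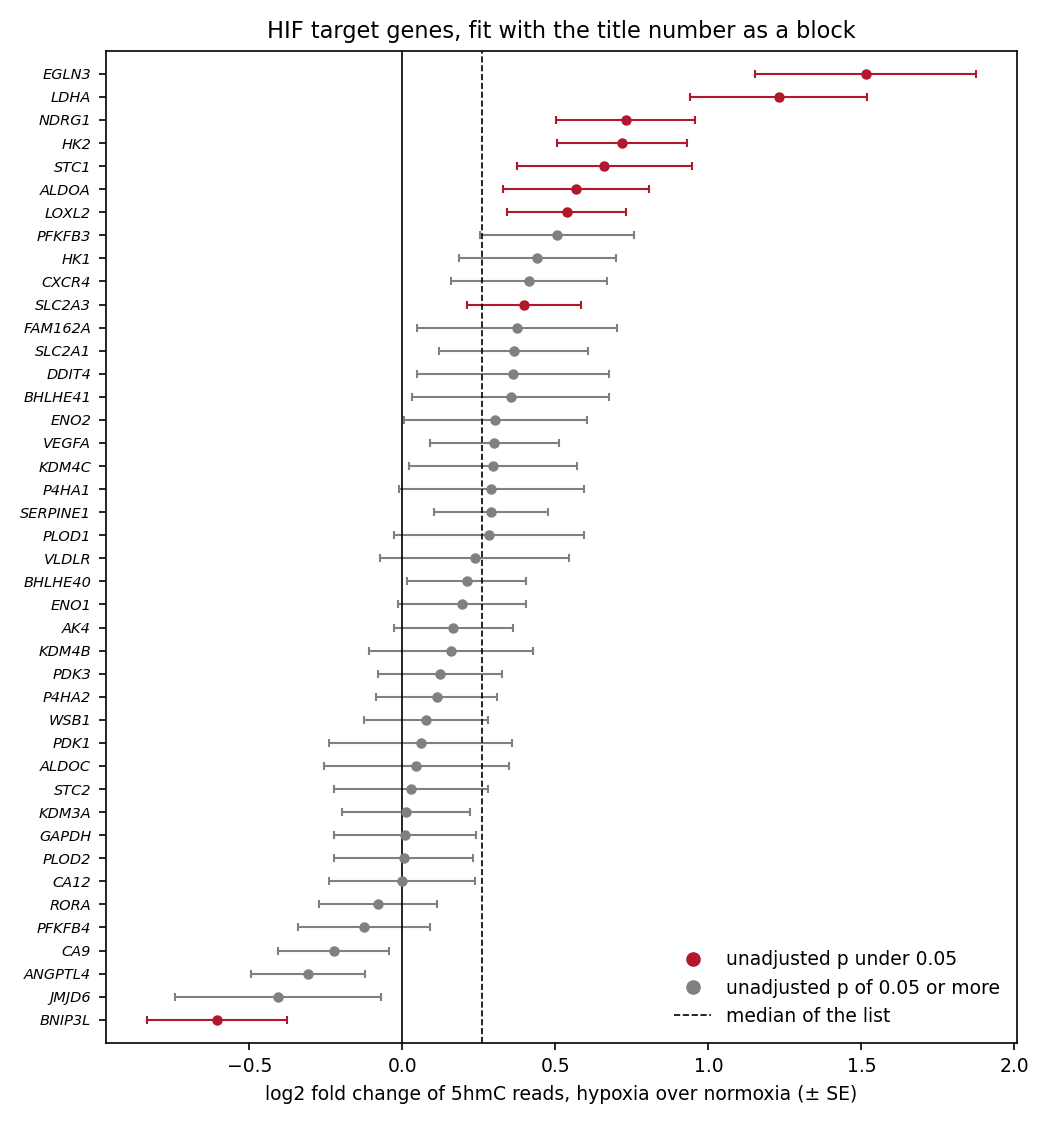
Log2 fold change of 5hmC reads, hypoxia over normoxia, for the 42 measured HIF target genes in the blocked fit, with points for the estimate and bars for its SE, and the dashed line at the list's median of 0.26. EGLN3 and LDHA lie at the top and BNIP3L at the bottom, with 35 of the 42 genes above 0.

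Genes of the extracellular matrix and TGF-beta signalling had, as a group, fewer 5hmC reads in hypoxia. Without the block 31 of 39 measured members had a negative log2 fold change, with a median of -0.221 and a camera adjusted p of 0.0382. With an estimated correlation the adjusted p was 0.649, and 0 members passed over all genes or adjusted over the list alone, with or without the block. LTBP1, which holds latent TGF-beta in the matrix, had 163 ± 18.6 CPM in hypoxia and 222 ± 32.8 in normoxia (SD, n = 6 each), a log2 fold change of -0.45 ± 0.191 (SE). The collagen genes COL12A1 (-0.53 ± 0.280) and COL3A1 (-0.45 ± 0.296) and the signal transducer SMAD3 (-0.62 ± 0.315) had values of the same sign. LOXL2, a collagen cross-linking enzyme gene also on the HIF list, had 0.52 ± 0.225. Leaving out any 1 of 8 libraries (hypoxia 110, 16 and 21, and normoxia 110, 16, 33, 49 and 4) ended the call, with adjusted p of 0.0677 to 0.423. So did testing without a count filter (0.0516) or among genes above the median of mean CPM (0.107), and, in the blocked fit, leaving out number 110 (0.192), 16 (0.0817) or 49 (0.0847). The blocked fits without a filter and above the median gave 0.00766 and 0.0446, and the blocked fit of all genes adjusted p = 0.485 with an estimated correlation.

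The other 15 of the 17 gene lists were not called, with camera adjusted p of 0.141 to 0.979 without the block. The inflammation and NF-kB list had 8 positive and 20 negative log2 fold changes (adjusted p = 0.141), and the stromal surface marker list 4 positive and 12 negative (0.615). The inflammation list was called without hypoxia 4 (adjusted p 0.0262; adjusted p = 0.514 with an estimated correlation) and, in the blocked fit, without number 4 (0.011; adjusted p = 0.312 with an estimated correlation). VCAM1, a cell adhesion receptor gene on both lists, had 50.7 ± 39.3 CPM in hypoxia and 103 ± 90.4 in normoxia (SD, n = 6 each), lower in 6 of 6 numbers. Its blocked log2 fold change of -0.95 ± 0.238 had an edgeR adjusted p of 0.0106 over the inflammation list alone, 0.00607 over the surface marker list alone and 0.225 over all genes. IFNGR1, an interferon-gamma receptor gene, had -0.49 ± 0.282 and ITGA1, an integrin gene, -0.31 ± 0.214 without the block. The smooth muscle and pericyte marker list had 3 positive and 5 negative members (0.615). ACTA2, smooth muscle actin, had 58.5 ± 44.3 CPM in hypoxia and 102 ± 84.0 in normoxia, and passed over that list alone in the blocked fit (log2 fold change -0.77 ± 0.221, adjusted p 0.0126) but not over all genes (0.354). CALD1, caldesmon, had -0.51 ± 0.329 without the block.

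For the cell cycle list, 4 members were positive and 15 negative (camera adjusted p = 0.151), and without normoxia 21 the list was called (adjusted p 0.0314; adjusted p = 0.342 with an estimated correlation). CDK1 had a log2 fold change of -0.57 ± 0.271 (SE) and BUB1 -0.72 ± 0.330. The senescence and apoptosis list had 5 positive and 15 negative members (0.42), among them MDM2 with -0.65 ± 0.398 and CDKN2C with -0.58 ± 0.386. The adipocyte program had 8 positive and 5 negative members (0.339). ADIPOQ, the adiponectin gene, had 240 ± 77.1 CPM in hypoxia and 160 ± 56.9 in normoxia (SD, n = 6 each), a log2 fold change of 0.60 ± 0.262, and PLIN2, a lipid droplet coat gene, -0.36 ± 0.220. The bone and cartilage program had 7 positive and 11 negative members (0.979), with MSX2 at -0.88 ± 0.479 and RUNX2, the osteoblast transcription factor, at -0.34 ± 0.216. The mitochondria list had 4 positive and 9 negative members (0.741), with NDUFA9 at 0.54 ± 0.328 and SDHC at -0.51 ± 0.320.

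For the angiogenesis list, 12 members were positive and 21 negative (camera adjusted p = 0.615). The vascular receptor gene FLT4 had a log2 fold change of 0.68 ± 0.302 (SE) and ROBO4 -0.82 ± 0.292, with ROBO4 lower in 6 of 6 numbers. Endothelial markers had 5 positive and 4 negative members (0.635), with CDH5 at 0.40 ± 0.307. Immune cell markers had 8 positive and 2 negative members (0.141), with IKZF1 at 0.40 ± 0.257 and PTPRC, the pan-leukocyte antigen CD45, at 0.37 ± 0.263. Neuronal genes had 9 positive and 5 negative members (0.141), with RBFOX1 at 0.48 ± 0.318 and NLGN1 at 0.43 ± 0.333. Without normoxia 21 the neuronal list was called (adjusted p 0.000694; adjusted p = 0.342 with an estimated correlation), as in the blocked fit without number 21 (0.00052; adjusted p = 0.441 with an estimated correlation). Epithelial markers had 2 positive and 2 negative members (0.615), with CDH1 at 0.27 ± 0.239 and ESRP2 at -0.17 ± 0.333.

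The enzymes that write, oxidise and erase DNA methylation were not called as a group, with 3 positive and 11 negative members (camera adjusted p = 0.741). TET1, TET2 and TET3, the dioxygenases that make 5hmC, had log2 fold changes of -0.09 ± 0.244 (SE), -0.04 ± 0.248 and -0.15 ± 0.327 at their own genes, and TET2 was at 0.03 with library size as the only scaling. DNMT1, the maintenance methyltransferase, had 61.9 ± 22.1 CPM in hypoxia and 87.6 ± 48.2 in normoxia (SD, n = 6 each), a log2 fold change of -0.51 ± 0.328. DNMT3A stood at -0.16 ± 0.288 and DNMT3B at -0.02 ± 0.280, the latter at 0.04 in the blocked fit. IDH2, a mitochondrial isocitrate dehydrogenase gene, had 0.57 ± 0.399. Of the oxygen-sensing genes, 7 were positive and 6 negative (0.635). HIF1A had 188 ± 51.1 CPM in hypoxia and 172 ± 80.9 in normoxia, EPAS1 34.5 ± 22.4 and 42.7 ± 30.2, and ARNT2 had a log2 fold change of -0.38 ± 0.280. EGLN3, also on this list, was its 1 member to pass adjusted over the list alone in the blocked fit (adjusted p 0.00263).

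The second comparison asked whether hypoxia changed how much of the genome was called as 5hmC peaks. Gene counts were scaled to each library's size and peak numbers followed its reads, so neither measures the total amount of 5hmC. Hypoxia libraries had 192800 ± 27700 peaks and normoxia libraries 181300 ± 51700 (SD, n = 6 each; two-sided exact permutation p = 0.645 over 924 arrangements), with the hypoxia library higher in 3 of 6 numbers. Peaks covered 78.1 ± 10.7 Mb in hypoxia and 79.26 ± 14.5 Mb in normoxia (exact permutation p = 0.874, Benjamini-Hochberg adjusted p = 0.874 with median width). Median peak width was 324.3 ± 37.5 bases in hypoxia and 358 ± 104 in normoxia (exact permutation p = 0.604, adjusted p = 0.874). In a comparison not among those fixed beforehand, none of chromosomes 1 to 18 and X passed for a different share of peaks between groups (19 exact permutation tests, adjusted p of 0.955 at the lowest). The normoxia library of number 21 had 104718 peaks of 556 bases median width. Without it, the difference in peak number turned to -3800 and that in width to 5.93 bases.

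The number of peaks followed the number of reads. Over the 12 libraries Pearson's r was 0.876 (permutation p = 0.00021) and Spearman's rho 0.923 (permutation p = 7e-05), the 1 relation of this kind computed. Without the libraries farthest from the median read count, both of number 4, r was 0.928. It was 0.808 within the hypoxia and 0.907 within the normoxia libraries, and 0.926 within sequencing lane 7. Within lane 8, with the 4 libraries of numbers 49 and 4, r was 0.824 (permutation p = 0.165).

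**Figure D3:**
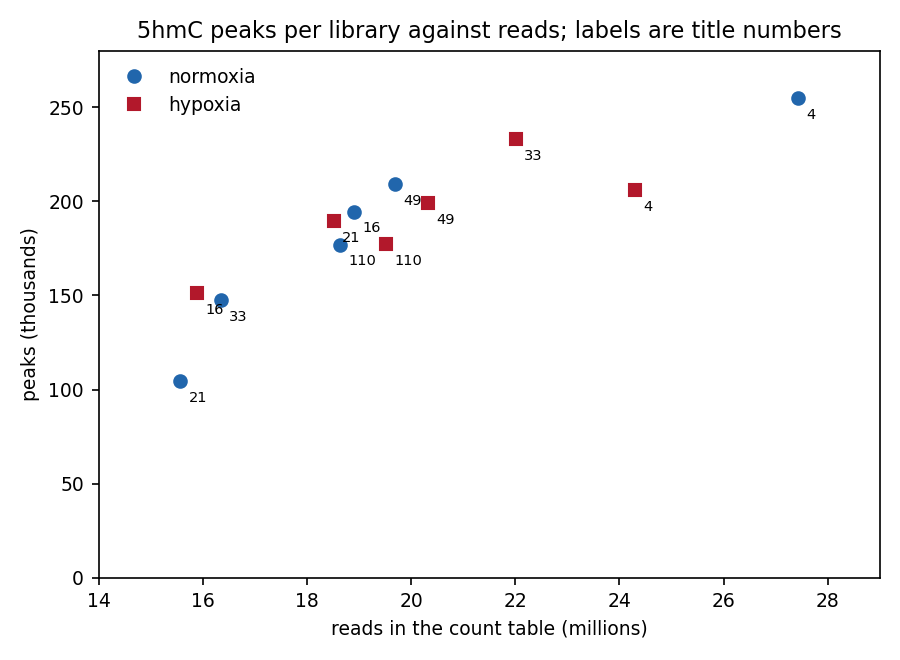
Peaks per library against the reads in its count table, with circles for normoxia, squares for hypoxia and title numbers as labels. The lists run from 104718 peaks in normoxia 21 to 254811 in normoxia 4, the libraries with the fewest and the most reads.

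The third comparison looked for regions with a peak in most libraries of 1 group and few of the other. The lists merged into 409760 regions, of which 32883 (8.02%) had a peak in all 12 libraries and 116016 in 1. In 1059 regions at least 5 hypoxia and at most 1 normoxia libraries had a peak, and in 280 regions the reverse held. With the same number of top peaks from each list the sides held 760 and 324 regions, and at 4 libraries against 1 they held 4228 and 2517. Other groupings of the libraries gave as many such regions in 61 of 100 splits (the real one included). The splits compared the total of both sides, so the larger count on the hypoxia side was not tested. No count without normoxia 21, the list with the fewest peaks (104718), is given here. Peaks in 6 of 6 hypoxia and 0 of 6 normoxia libraries were found in 12 regions, and the reverse in 0. As many such regions came from 59 of 100 splits and from 14 of 32 swaps within numbers, the real grouping included. By length, the first of the 12 were on chromosome 4 (15042148 to 15042791), chromosome 13 (69656817 to 69657377), chromosome 7 (4239415 to 4239973), chromosome 2 (137104799 to 137105353) and chromosome 5 (49428477 to 49428969). On the normoxia side, regions on chromosome 13 (31830816 to 31832339), chromosome 16 (65795425 to 65796644) and chromosome 6 (49692267 to 49693344) had a peak in 5 normoxia and 0 hypoxia libraries, and regions on chromosome 1 (9846834 to 9847819) and chromosome 15 (55400905 to 55401847) in 6 and 1. The genome build is not given in the sources used here, so no gene was assigned to these regions. No single region was tested.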

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

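The count of lists over swapped numbers and the comparison of normoxia 21 with a library of similar depth were chosen after the result was seen, as were the repeat of the thinning over 20 draws and the weight given to abundant messengers. The predictions of the other tests below were written before their values were seen.

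The rise of HIF target genes in hypoxia with the block had a camera p of 5.64e-07, and its call was lost (adjusted p = 0.485 with an estimated correlation). Swapping hypoxia and normoxia within numbers gave as small a p in 2 of 32 arrangements, the real one included, and the smallest of the others was 7.23e-08, with 1 number swapped, so chance cannot be excluded. A difference in library depth is argued against: with all libraries thinned to 263578 gene reads, the list's camera p was at most 0.00675 over 20 draws, with a median log2 fold change of 0.151 to 0.247. Reads carried over from RNA stay open. Ribosomal protein genes ranked low (median percentile 36.9 of read count), under the bound written beforehand, but they can lose reads to pseudogenes. Of 10 other abundant messengers, 6 ranked above percentile 75: COL1A1 (98.4), SPARC (96.9), COL1A2 (94.4), VIM (91.8), GAPDH (90.6) and ACTB (84.1). Below it were FTH1 (64.2), TMSB4X (59.4), TPT1 (37.2) and EEF1A1 (24.4). Read counts were not corrected for gene length, so these ranks cannot tell reads from RNA from reads from DNA. An effect of hypoxia on 5hmC at these genes also stays open, as a hypothesis.

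The normoxia library of number 21 stood apart on the first principal component, with 30.8% of the variance, by a gap of 0.556 of the range. Its share of reads in genes was the lowest in its group (1.69% against 2.48% for the next, gap over range 0.658), its share with low alignment quality the highest (10.3% against 6.21%, 0.662), and its peaks the widest (556 bases against 359, 0.659). Its low depth alone is argued against: after thinning of all libraries the gap was still at least 0.415, above the bound of 0.4 by little, and the hypoxia library of number 16, with a read total within 5% of its own, had 1.44 times as many peaks. A poorer capture or library may lie behind it, which was not tested, and no biological explanation was tested.

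For the 4 genes called with the block, 1 of the 32 arrangements, the real one, gave as many, the smallest share possible here, and the highest other gave 0. With 32 arrangements no smaller share can be reached, so chance is not excluded, and the share covers the edgeR count alone. DESeq2 with the block gave 0 calls, with 4 genes at an adjusted p under 0.10 (lowest 0.072). Thinned counts gave 0 calls (median), with at least 1 call in 9 of 20 draws. For the 2 gene lists called with the block, 7 of the 32 arrangements gave as many (highest other 3), and for the 2 called without it, 24 of 100 splits (highest other 5), so chance cannot be excluded. For the 324 genes at an unadjusted p under 0.05 without the block, 60 of 100 splits gave as many, and the highest counts among the others, 2165 such genes and 122 calls, point to a structure of the samples other than oxygen. Chance cannot be excluded for the 1339 regions with a peak mostly in 1 group either, with 61 of 100 splits giving as many and 8970 in the highest other.

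The gap between 1 library and the rest of its group was also large for other values. For normally distributed values, chance alone gives about 1 in 20 groups. Among library measures 4 of 22 groups were marked, 3 of them by normoxia 21 (above), and the 4th was the read total of normoxia 4 (27428482, gap over range 0.653). Among named genes 14 of 112 groups were marked, where 5.6 were expected by chance at that rate. CPM were not log-transformed and the genes share libraries, so no conclusion is drawn from the difference. Number 49 had the highest SFTA2 count in both groups, with 110.9 CPM in hypoxia (0.716) and 32.09 in normoxia (0.636), the latter on few reads. Normoxia 21 had the highest CPM in its group for TET2 (173.9, 0.715), DNMT3B (144.9, 0.705) and MSX2 (169, 0.691). Normoxia 33 had the highest for MMD (391, 0.70) and ITGA1 (404.8, 0.67), normoxia 4 for ROBO4 (60.1, 0.632) and normoxia 16 for IKZF1 (170.5, 0.858). In hypoxia, number 21 had the lowest NDUFA9 (13.72, 0.808) and the highest BUB1 (27.44, 0.737), and number 49 the highest CDKN2C (63.03, 0.76). Number 110 had the lowest ESRP2 (14.87, 0.633) and number 4 the lowest NLGN1 (19.96, 0.659).

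The peak totals compared above include peaks on chromosome Y and the mitochondrial chromosome, whose shares were not compared. Although the animals were female, each library had 176 to 365 peaks on chromosome Y, 96.6 to 99.2% of them in its first 10 Mb. Each also had 2 to 6 peaks on the mitochondrial chromosome.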

How the results depend on the processing

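Counts of calls from thinned reads, and the blocked fit as a reference of its own, were chosen after seeing the data. Without the block, the count of called genes was 0 under every scaling, filter, covariate, tool and left-out library tried. The block gave 4, with RLE or library-size scaling 4 (the same 4 genes), and without a count filter 9 (all 4 among them). Set beside those 4 calls, DESeq2 with the block gave 0 among 25337 genes, with 4 at an adjusted p under 0.10. In that fit SFTA2, PPP1R3C and SHMT2 had log2 fold changes of 2.67, 1.3 and 1.17, each with an adjusted p of 0.072. Thinned counts gave 0 calls (median of 20 draws, highest 4), and leaving out 1 number gave 0 to 12. The cause was not tested, though thinning removes reads and leaving out a number removes libraries.

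The 2 lists called became 1 without a count filter (HIF targets), 1 with the block and thinned counts together (median), and 0 with an estimated correlation, with fry and among genes above the median of mean CPM. With the block, 2 were called without a filter and 2 above the median of mean CPM, and fry's mixed test, not its directional one, called HIF targets (0.0413), matrix genes (0.0446), mitochondria and smooth muscle markers (0.0287 each). Leaving out 1 library or number gave 1 to 4, and HIF targets were called in all 12 and all 6 of these fits, but in 0 with an estimated correlation (adjusted p 0.0955 to 0.639, and 0.312 to 0.626 with the block). The 4 (without normoxia 21) added the cell cycle and neuronal lists, and leaving out hypoxia 4, or number 4 with the block, added inflammation. With the block, the median log2 fold change of HIF targets was 0.26 with a camera adjusted p of 9.59e-06. That call was lost with an estimated correlation (median 0.26, adjusted p 0.485), and thinned counts gave adjusted p of 0.000279 to 0.078, above 0.05 in 1 of 20 draws. Apart from these and the calls in the report, the block changed no other call.

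Leaving out 1 library moved the difference in peak number from -3800 (without normoxia 21) to 26200 (normoxia 4), in Mb from -6.21 (normoxia 33) to 1.93 (hypoxia 16), and in median width from -53.9 (normoxia 33) to 5.93 bases (normoxia 21), with no p under 0.05. The 1339 regions became 12 at 6 against 0, and 6745 at 4 against 1; the replicate block, as swaps within numbers, gave a median of 857 under exchanged labels, and 12 of 32 gave as many as 1339. Of 560 values of the 56 named genes, 532 kept direction and side, 19 (7 genes) passed the threshold, all with the block, and 9 (TET2 and DNMT3B) crossed 0 with no call. Shares of peaks by annotation and the fit on autosomes and X alone were not run.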

Other observations

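With number 21 left out, a setting chosen after seeing the data, the blocked fit called 12 genes. Besides the 4 called with all numbers, these were EGLN3, the oxygen-sensing prolyl hydroxylase, higher in hypoxia, and JAZF1, MMD, PPBP and HS3ST3B1, a heparan sulfate sulfotransferase gene, lower in hypoxia, with 3 further genes without a symbol. With all numbers, HS3ST3B1 had a blocked log2 fold change of -0.89 and an adjusted p of 0.226. The blocked fit without a filter on low counts also called EGLN3, JAZF1, MMD, a gene without a symbol, and ACKR3, a scavenger receptor for chemokines.

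The genes next to HIF targets were also compared, a test not among those fixed beforehand. For the 8 HIF targets with a positive blocked change and an unadjusted p under 0.05, the 7 neighbouring genes that were tested had a median log2 fold change of 0.046. That median was at percentile 71 of 10000 random lists of the same size, and 0 of the neighbours were called.

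Some libraries resembled those of other numbers more than their own. Of the 12 libraries, 9 correlated best with the other library of their own number in deviations of log2 CPM. Hypoxia 33 correlated at 0.504 with normoxia 4 and at 0.417 with normoxia 33, and hypoxia 4 at 0.414 with normoxia 33 and at 0.136 with normoxia 4. In bases under peaks, the Jaccard index of libraries with the same number was 0.442 on average against 0.363 for others (one-sided exact permutation p = 0.00417 over 720 arrangements). It was 0.508 for hypoxia 33 and normoxia 4, and 0.368 for hypoxia 33 and normoxia 33, but 0.449 for hypoxia 4 and normoxia 4 and 0.385 for hypoxia 4 and normoxia 33. For hypoxia 21 it was 0.506 with normoxia 16 and 0.349 with normoxia 21. In gene counts, hypoxia 33 and hypoxia 4 each correlated more with the normoxia library of the other's number. In peaks this held for hypoxia 33 alone. Exchanging the numbers 33 and 4 within 1 group would raise the same-number mean of both measures. Whether these labels were exchanged was not tested further. The blocked fit, with 0 calls when either number was left out, rests on those labels.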
